A study of Mus musculus with 4 samples.

How the data were processed

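YAP, a transcriptional co-activator that binds DNA through TEAD proteins, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse epidermis. Epidermal cells came from the skin of adult mice of 18 to 25 weeks, wild type (WT) or knockout (KO) for Bmal1 per the labels, collected at Zeitgeber time 4 (ZT4, 4 hours after lights on). BMAL1 is a core activator of the circadian clock. The labels' genotype field says Bmal1 KO and their treatment protocol Bmal1cKO, and in which cells the gene was deleted is not given in the sources used here; KO below stands for the library so labelled. Per the labels' protocols, 30 M cells were fixed for 30 min with a Gold fixative and then for 10 min with 1% formaldehyde, and 30 µg of chromatin was precipitated with an anti-YAP antibody. Libraries were read as 51 bp single reads on a NextSeq2000, with 25 to 50 M reads per sample per the labels. The labels name 4 samples, a YAP ChIP and an input for each genotype. The 2 ChIP samples each have 1 peak list and no file of the 2 inputs was used here.

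The submitters' processing notes name Trimmomatic 0.36, SAMtools 1.5 and MACS2 2.1.1, with the mouse build mm10, without giving their roles. The aligner, the controls and the filters are not given in the sources used here. The peak names carry the word pooled, and what was pooled is not given in the sources used here. Each list is in a 10-column layout without a header. The deposited score of a peak is 10 times its −log10 q, truncated to a whole number. The deposited fold is the ratio of the signal at the summit, the highest point of the peak, to the caller's background. The authors' files also give the −log10 p and −log10 q of each peak and the distance of its summit from the peak start. The lowest −log10 q lies just above 2 in both lists, a q limit of 0.01. These fold, score and −log10 values are the authors' and were used to rank and filter peaks within a list and, in alternatives, to set equal limits in both lists.

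Fold and p of a peak caller with Poisson scoring depend on the whole number of reads at the summit, on the scaling of ChIP to input and on the background. The scaling of each list was therefore searched for, and the reads and the background at each summit were solved from fold and p. A whole number of reads matched the −log10 p within 0.002 in 100% of peaks of both lists, against 0.93% (WT) and 0.40% (KO) with the scaling set 3% off. The recovered scaling was 0.694 for WT and 0.842 for KO. The recovered background of evenly spread ChIP reads was 9.63 per 300 bp in both pools. Both ChIP pools therefore had the same depth in these units. With the caller's preset genome size and reads extended to 300 bp, which are assumptions, this background corresponds to 60.0 M ChIP reads in each list, above the 25 to 50 M per sample of the labels. Whether this reflects pooling, those assumptions or reads drawn down to a common number is not given in the sources used here, so recovered reads are comparable between the lists only in these units. The matching input background was 6.68 per 300 bp for WT and 8.10 for KO. On simulated lists of 36576 and 14879 peaks, the same procedure returned the exact reads of 100% of peaks. These lists were made with the formulas that the procedure inverts. They check only the search and the solving, not whether the deposited lists follow those formulas. Recovered reads were the basis for setting the lists beside each other. The comparison of recovered reads, in place of the authors' fold or score, across lists, the limit of 120 WT reads for strong sites, the KO to WT ratios and the matching of gene lists on reads were chosen after seeing the data.

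A WT peak was called kept when it overlapped a KO peak by at least 1 bp, and WT-only otherwise. KO peaks were called shared or KO-only in the same way. The counts were the same with bedtools 2.31.1. For the KO to WT ratio, a kept peak was paired with the strongest overlapping KO peak, a rule that replaced, after the ratios had been seen, a first rule of the KO peak with the largest overlap, which could pair a summit with a minor KO peak. The even-spread background of 9.63 reads was subtracted on both sides. Chance overlap came from 100 seeded random placements of the KO peaks on the same chromosomes. Intervals are exact 95% Clopper-Pearson intervals and cover counting error only; those of differences in log2 ratio come from resampling sites. With 1 pool per genotype there is no replicate spread, so no test was run and no p-value is given.

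Gene spans came from an NCBI RefSeq table of the assembly GRCm38.p6, the build called mm10, with 21631 protein-coding genes on chromosomes 1 to 19 and X. The table gives no strand, exons or sequence. Each summit was linked to the nearest gene span within 100 kb. The design set before the data were examined named transcription starts. In their place, a summit within 2 kb of either end of a gene span was counted as near a gene end, and the alternative of 5 kb upstream became 5 kb on either side. The planned motif shares and their 4 alternatives were not run. The nearest gene need not be the gene a site acts on.

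Before the data were examined, 17 gene lists with 416 names were fixed. Of these names, 4 were found by a synonym, 5 were not found among the protein-coding genes and 1 was a duplicate. The share of a list's genes with a WT peak was set against 10000 random lists matched on the length of sequence nearest to each gene, in 10 bins. The share of its WT peaks that were kept was set against 10000 random sets of WT peaks matched on WT score decile. Both are given as percentiles, which describe these lists and are not tests. On simulated sets of 150 peaks, 13 of 200 sets without an effect and 200 of 200 sets with 20 percentage points more kept peaks fell outside the central 95% of random sets. The simulated and the matched sets of peaks were drawn peak by peak. Clustering of several peaks at 1 gene, as in the gene lists, is therefore not covered. Named genes were those of the 8 highest-scoring peaks of each class, and from each list up to 2 genes with the highest-scoring kept peak and up to 2 with the highest WT peak among genes without a kept peak. Predicted genes were skipped, and 1 gene that this rule names is not reported here. Any gene of the YAP/TEAD and clock lists could be named, with Bmal1 (Arntl) first. Positions are 1-based on mm10. Alternatives covered the overlap rule, stricter lists, equal list lengths, merging, autosomes, the linking distance and the matching. Some genes stand in more than 1 list, among them Tgfb2, Fosl1, Sox9, Thy1 and Ptprc. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.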

Results

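YAP binding was compared between the epidermis of Bmal1 WT and Bmal1 KO mice at ZT4, to ask which YAP sites called in WT were also called in KO. Each genotype had 1 pooled list of peaks, so no value below has a replicate error. The WT list held 36576 peaks covering 22.2 Mb and the KO list 14879 peaks covering 7.45 Mb. Median peak width was 516 bp in WT and 448 bp in KO. Recovered summit reads had a median of 61 in WT and 52 in KO.

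Arntl, the gene that encodes BMAL1, had 15 linked WT peaks, of which 9 were kept in KO. The peak with the most reads lay on chromosome 7 from 113085851 to 113086870, 92100 bp outside the gene span, with 153 WT and 126 KO reads. Above background its log2 KO to WT ratio was -0.30, the highest of the kept peaks at this gene. Inside the span, the peak with the most reads, from 113235993 to 113236632, had 123 WT and 65 KO reads (-1.03). The lowest ratio, -1.33, was at the inside peak from 113195151 to 113195792, with 121 and 54 reads. Another inside peak, with 59 and 46 reads, had -0.44. YAP peaks do not read out the Arntl transcript or its deleted part, so these values do not check the genotype labels.

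YAP sites in KO were fewer, and nearly all of them overlapped a WT peak by at least 1 bp. The WT list was 2.46 times as long as the KO list. Of the WT peaks, 14315 (39.1%, 95% interval 38.6 to 39.6) overlapped a KO peak and 22261 did not. This share depended on the length of the WT list: it was 77.8% with the WT list reduced to the number of KO peaks by score, and 68.9% for the higher-scoring 50% of WT peaks. Of the KO peaks, 14726 (99.0%, 98.8 to 99.1) overlapped a WT peak and 153 did not. The KO share was also lower with 50% reciprocal overlap and with the reduced WT list, as given in the section on processing. Random placement gave overlap for 0.705% of WT peaks and 1.71% of KO peaks. Equal limits on recovered reads widened the ratio of peak numbers, to 4.64 at 80 reads (10500 against 2262 peaks) and 7.57 at 120 reads (3692 against 488 peaks). It was 4.93 and 6.004 at a fold of at least 8 and 10, and 3.97 at a −log10 q of at least 40.

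Whether a WT peak was kept followed its strength. By WT score decile, the kept share rose from 2.73% in the lowest decile to 48.9% in the seventh and 99.7% in the highest. By recovered reads it was 1.27% under 40 reads, 31.8% at 60 to 69 reads and 96.8% at 100 to 119 reads. All 1671 WT peaks with at least 150 reads were kept (lower bound 99.8%).

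**Figure D1:**
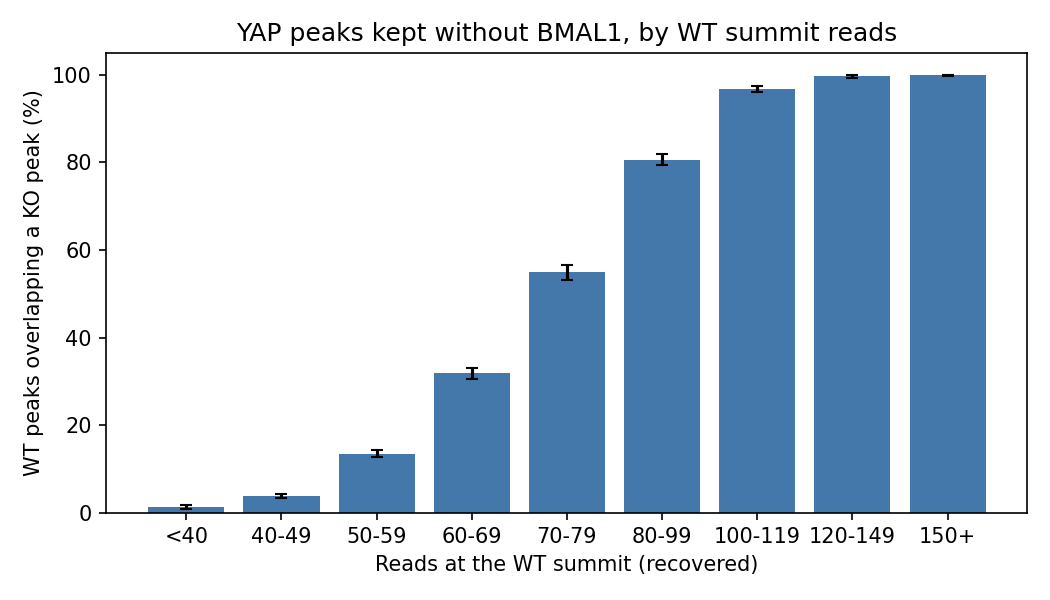
Share of WT peaks that overlap a KO peak (%, vertical axis) by recovered reads at the WT summit (horizontal axis); bars are shares and whiskers exact 95% binomial intervals. The share rises from 1.27% under 40 reads to 100% at 150 reads and above.

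At strong sites, KO summits held fewer reads than WT summits. Among 3692 WT peaks with at least 120 reads, 3686 were kept, with a median of 146 reads in WT and 84 in KO. Above background, the median KO to WT ratio was 0.543, a log2 value of -0.88 (interquartile range -1.05 to -0.73). KO reads above background were lower in 3685 of the 3686 sites. The spread of the log2 ratio was 0.248 (SD between sites), against 0.220 from counting alone. The ratio was less reduced at stronger sites, with a median log2 of -0.96 in the weakest of 5 equal bins of these sites and -0.75 in the strongest.

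**Figure D2:**
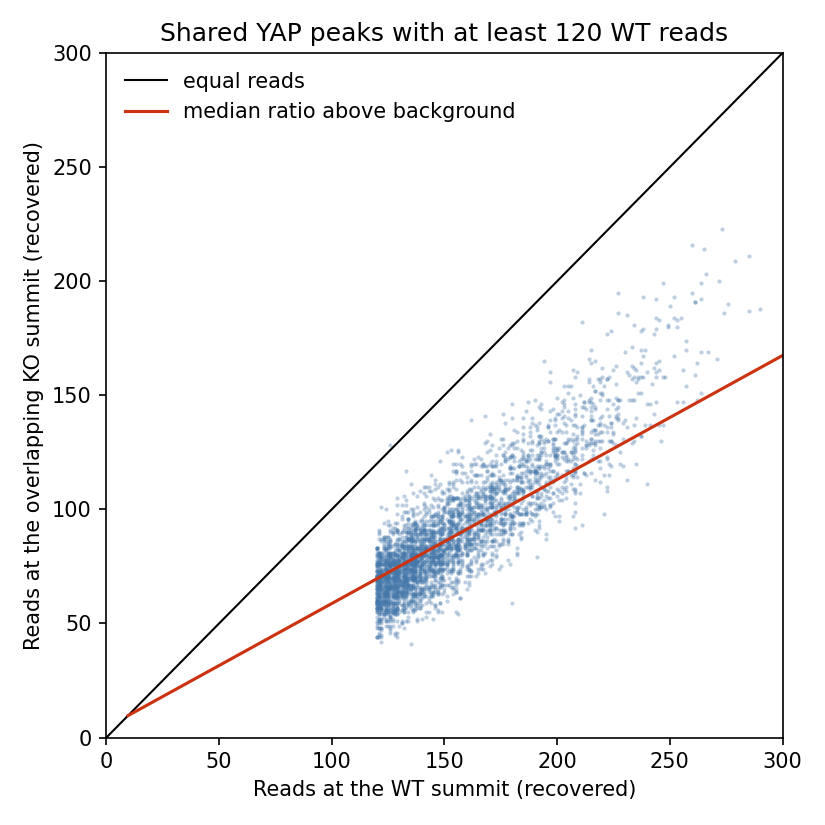
Recovered reads at the KO summit (vertical axis) against reads at the WT summit (horizontal axis) for the 3686 kept WT peaks with at least 120 reads, 1 point per peak. All but 1 point lie below the black line of equal reads; the red line has the median ratio of 0.543 above background, and the points with the most reads lie mostly above it.

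The highest-scoring shared sites were linked to Dnm3, Mzb1, Actr3, Pld1, Tbc1d16, Ky, Colec10 and Jmjd4. The site in Dnm3, which encodes a dynamin, lay on chromosome 1 from 162388461 to 162389561, inside the gene span, with 276 WT and 190 KO reads. The site near Actr3, which encodes a subunit of the actin-nucleating Arp2/3 complex, lay on chromosome 1 from 125482465 to 125483616, 47334 bp outside the gene span, with 266 and 203 reads. The highest WT-only sites were linked to Bag3, Jund, Edaradd, Cuedc1, Macroh2a1, Zfp160, Tnip1 and Tuft1. The site 6395 bp from Bag3, a co-chaperone gene, lay on chromosome 7 from 128553097 to 128553643 with 131 WT reads. The site 2163 bp from Jund, a gene of the AP-1 transcription factors, lay on chromosome 8 from 70695211 to 70695837 with 127 WT reads. Only 6 WT-only sites had at least 120 reads, those near Bag3, Jund, Macroh2a1, Edaradd, Nav2 and Rtn4r; Nav2 and Rtn4r were named after their values were seen. KO-only sites were weak, with at most 53 reads; the highest were linked to Epb41l4a, Prkar2a, Nek7, Nsmce2, Hspg2, Pef1, Plagl1 and Irf1.

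YAP/TEAD target and pathway genes carried YAP sites in WT more often than matched genes, and their sites were kept about as often as other sites of equal score. Of 36 such genes, 33 had a WT peak and 29 a KO peak, against 58.6% of genes at random for WT. Of their 232 WT peaks, 110 (47.4%, 40.8 to 54.1) were kept, against 48.1% for matched peaks (36.8th percentile). Strong sites included Ajuba (chromosome 14, 54575256 to 54576250; 273 WT and 223 KO reads), which encodes a LIM protein that restrains LATS kinases. The site at Lats2, which encodes such a kinase, had 241 and 137 reads. Amotl2 had 17 WT peaks, 12 of them kept, and Tead1 had 17, with 10 kept. Ccn2, a much-used YAP reporter gene, had 1 WT peak, 31 bp from the gene span, with 48 reads, and it was WT-only. Ankrd1, F3 and Nf2 also had WT peaks without a kept one, the highest-scoring with 46, 43 and 51 reads. Few WT peaks of this strength were kept anywhere: 3.82% from 40 to below 50 reads and 13.4% from 50 to below 60.

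Clock genes were linked to YAP sites in WT for 26 of 29 genes, against 54.4% at random. They kept 60 of 134 WT peaks (44.8%, 36.2 to 53.6), against 39.4% for matched peaks (96.0th percentile). Cry2 and Npas2 had the highest-scoring kept peaks, with 223 WT and 158 KO reads at Cry2 and 186 and 119 at Npas2. The Cry2 peak was not kept under a rule of 50% reciprocal overlap, under which the list fell to the 16.8th percentile. Nr1d1, which encodes the repressor REV-ERBα, had 170 and 84 reads at a peak 345 bp from its span. Per2, Per3, Dbp, Ciart, Csnk1d and Tspo had WT peaks and no kept peak. The highest-scoring of these peaks were at Dbp with 74 reads and Per2 with 56. The highest-scoring peak had 57 reads at Tspo, 50 at Ciart, 50 at Csnk1d and 39 at Per3. Of all WT peaks, 54.9% were kept from 70 to below 80 reads, 13.4% from 50 to below 60 and 1.27% under 40.

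Inflammatory and NF-κB genes had a WT peak for 33 of 50 genes (66.0%, against 51.2% at random, 98.2nd percentile), a percentile that was 55.2 in the lowest of the alternatives tried. Of their 172 WT peaks, 87 (50.6%) were kept, against 44.6% for matched peaks (99.1st percentile). The percentile was 94.8 with matching on reads and 91.2 with the reduced WT list. At the 19 strong kept sites of this list, the median log2 KO to WT ratio was -1.02 (interquartile range -1.15 to -0.79), against -0.88 for all strong sites. These sites were not matched on reads, with which the ratio varies. The cell cycle list was lower still, at -1.06 over 7 strong kept sites. Tnfaip3, a brake on NF-κB, had a peak of 205 WT and 122 KO reads on chromosome 10 from 19052665 to 19054434, 38354 bp outside its span. Il1b had 208 and 127 reads at a peak 36621 bp outside its span. Csf2 had a WT peak of 68 reads and no kept peak.

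Epidermal genes also carried many YAP sites. A WT peak was linked to 23 of 25 basal keratinocyte genes, 30 of 33 differentiated keratinocyte genes and 21 of 23 hair follicle and stem cell genes. Kept shares were 47.1%, 55.9% and 43.0%, against 42.3%, 49.9% and 37.5% for matched peaks. At their 30, 25 and 13 strong kept sites, the median log2 ratios were -0.77, -0.94 and -0.73. Cdh3, encoding P-cadherin, had 245 WT and 183 KO reads, and Itga3 had 238 and 179. Krt77 had 200 and 116 reads and Klf4, a factor of terminal differentiation, 188 and 117. Plet1 had 216 and 146 reads. The peaks linked to Klf4 and Plet1 lay 46682 and 50232 bp outside the gene spans. Krt15, Lor, Alox12b and Gli1 had WT peaks and no kept peak, the highest-scoring with 72, 60, 66 and 60 reads. Of all WT peaks, 31.8% were kept from 60 to below 70 reads and 54.9% from 70 to below 80.

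Cytoskeleton and adhesion genes had a WT peak for 30 of 30 genes, AP-1 genes for 18 of 19, TGF-β and matrix genes for 24 of 28 and cell cycle genes for 25 of 30. All 4 lists lay above the central 95% of random lists. Their kept shares were 44.3%, 44.8%, 41.9% and 34.7%, at the 86.6th, 75.7th, 35.8th and 10.98th percentiles of matched peaks. With 50% reciprocal overlap, the first 2 of these percentiles were 11.01 and 3.985. Examples were Ctnnb1 (β-catenin; 211 WT and 133 KO reads), Mafk (208 and 109, not kept with reciprocal overlap), Itgb6 (195 and 108) and Cdkn2a (156 and 72). Rhoa, Atf7, Tnc and Ccne2 had WT peaks of 103, 65, 61 and 98 reads and no kept peak.

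Genes of 7 lists for other cell types and tissues were linked to WT peaks less often than the mean of random lists, beyond the central 95% for 2 lists. A WT peak was linked to 4 of 15 fibroblast genes (0.69th percentile) and 6 of 20 neuronal genes (0.425th), the 2 lists outside; in other settings the neuronal list reached the 8.64th. The values were 4 of 15 for Langerhans and antigen-presenting cells (4.08th), 4 of 11 for T cells (15.9th), 6 of 12 for melanocytes (27.8th), 6 of 14 for endothelium (12.8th) and 7 of 20 for liver (6.08th). Each in its own lowest alternative, the Langerhans, T cell, melanocyte and liver lists also lay below the central 95%, at the 0.335th, 0.525th, 2.205th and 0.47th percentiles. Between 8 and 37 WT peaks were linked to each of these lists, too few for a precise kept share. Kept peaks included those linked to Epcam (148 WT and 76 KO reads), Mitf (84 and 51), Pecam1 (87 and 40, not kept with reciprocal overlap), Map2 (162 and 87) and Pck1 (137 and 57).

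**Figure D3:**
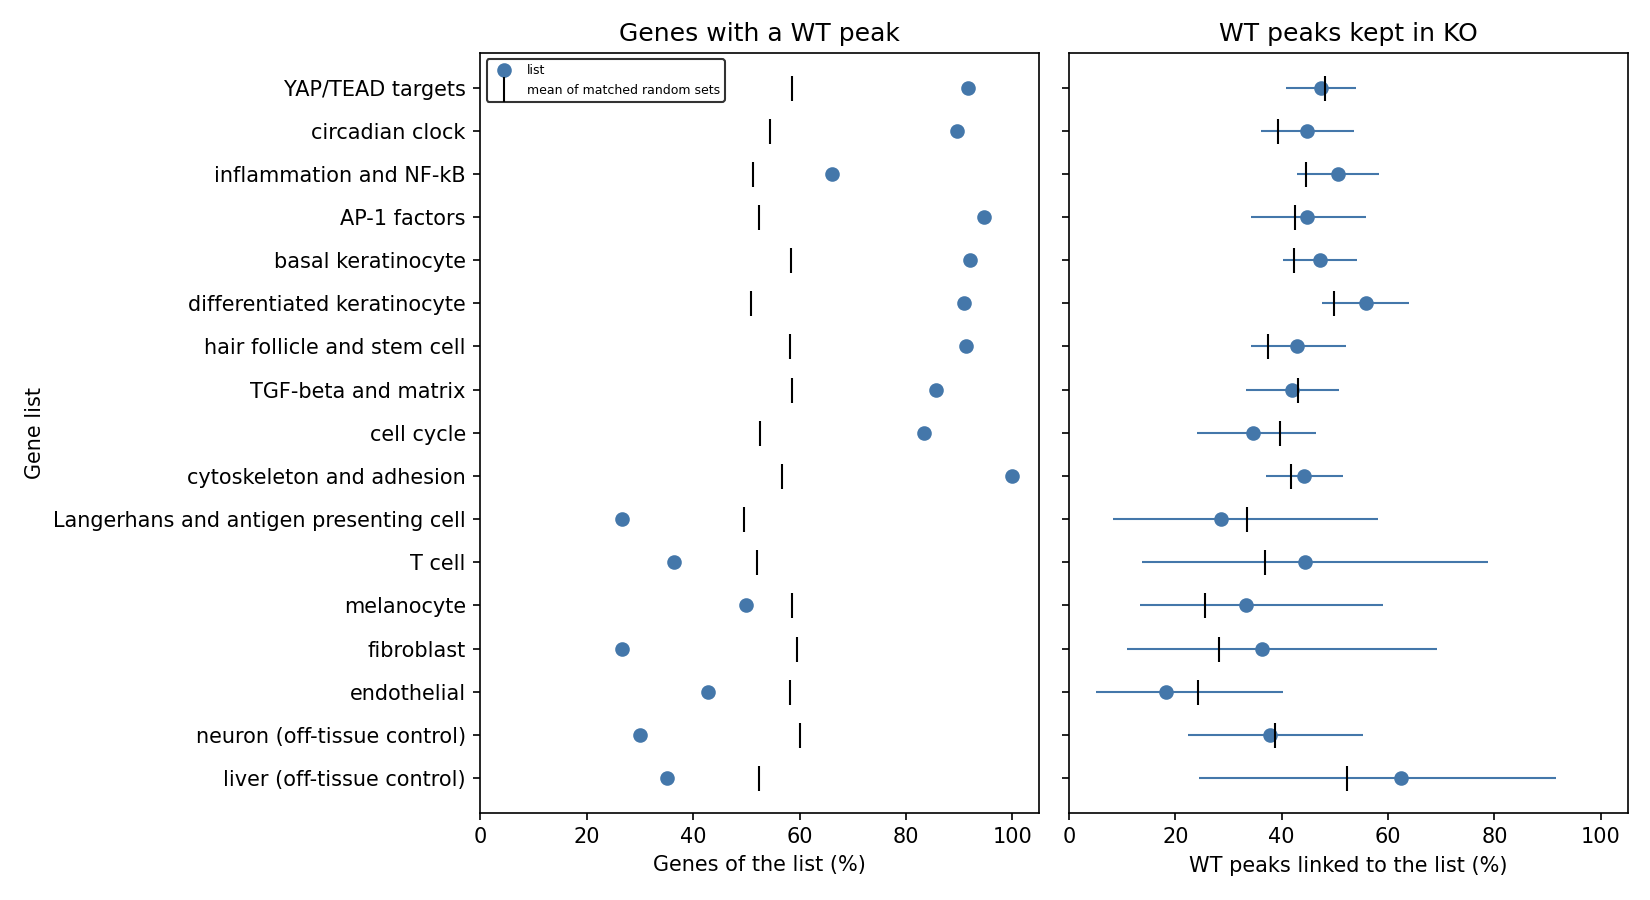
Left, share of each list's genes linked to a WT peak (%); right, share of the WT peaks linked to the list that were kept in KO (%), with exact 95% binomial intervals. Dots are the lists and ticks the means of 10000 matched random sets. Epidermal, YAP, clock and cytoskeletal lists lie to the right of their ticks on the left, while on the right the tick lies within the interval of every list.

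For the kept share, 3 of the 17 lists lay outside the central 95% of matched sets, all above it: inflammation and NF-κB, basal and differentiated keratinocyte genes. With the WT list reduced to the number of KO peaks no list lay outside, and with matching on reads the basal list and, in place of the others, the hair follicle and stem cell list did.

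WT peaks lay near a gene end more often than KO peaks, at 27.2% (26.8 to 27.7) against 22.7% (22.0 to 23.4), and 6.18% of random positions. The share was 22.6% for kept and 30.2% for WT-only peaks. Weighted to the score deciles of kept peaks, the WT-only share was 20.1%. That value rests heavily on the few WT-only peaks of the top decile, where 3646 of 3657 WT peaks were kept. No interval was computed for it, so it gives no order between kept and WT-only peaks. Matched on reads instead, 37.2% of peaks near a gene end were kept, against 39.9% elsewhere. Inside gene spans lay 53.3% of WT and 50.9% of KO peaks.

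By chromosome, the kept share lay between 36.5% on chromosome 6 and 41.5% on chromosome 9 among autosomes. Chromosome X kept 29.8% (25.7 to 34.2) of its 466 peaks, against 32.1% from their scores. On chromosome 7, which carries Arntl, 38.9% were kept against 39.3% from scores, and 7 peaks were KO-only.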

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

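Alternatives on recovered reads, on the strong sites and their pairing, and on the overlap rule and autosomes within score deciles were chosen after seeing the data; the others were set before. The WT list stayed longer than the KO list under every limit tried. The ratio of peak numbers was 4.93 and 6.004 at a fold of at least 8 and 10, 3.97 at a −log10 q of at least 40, and 4.64 and 7.57 at 80 and 120 reads. The share of WT peaks overlapping a KO peak was 32.1% with 50% reciprocal overlap, 37.9% with summits within 200 bp, 39.7% for the top part of each list, 40.7% with merging, 68.9% for the top WT peaks against all KO peaks and 77.8% with the WT list reduced to the number of KO peaks. The share of KO peaks overlapping a WT peak was 79.0%, 93.2%, 98.7% and 80.5% with reciprocal overlap, summits within 200 bp, the top part of each list and the reduced WT list, and 99.97% for the top KO peaks against all WT peaks. The top score decile kept 87.0% with reciprocal overlap and 98.9% with summits within 200 bp, and the bottom decile 2.13% with reciprocal overlap. Near a gene end lay 17.1%, 33.3%, 18.6% and 21.2% of kept peaks, and 24.4%, 40.5%, 31.3% and 25.6% of WT-only peaks, at 1 kb, at 5 kb, with reciprocal overlap and with the reduced WT list. The median log2 KO to WT ratio was -0.92 from 100 reads, -0.80 from 150 reads and -0.80 without background subtraction. It was -0.88 with the KO peak of largest overlap. The cause of these shifts was not tested, except that the reduced list holds only higher-scoring WT peaks. The count of 3 lists outside the random range for the kept share fell to 0 with the reduced WT list. It was 3 at 10 kb, 3 with reciprocal overlap, 2 with width matching and 2 with read matching, but of the 3 lists reported only 1, 2, 2 and 1 were among them, so no list's kept share held throughout. Of the 10 lists with more WT peak genes than random lists, 9, 9 and 10 were also above at 10 kb, within 5 kb of the gene and for the top WT peaks; inflammation and NF-κB was the list lost in the first 2; below random lists, other lists joined or left with the setting. Among the alternatives of the main results, 31 values moved beyond the interval of the reported value or, for ratios and counts, a fixed factor, and 25 did not. For named peaks, 22 values changed their overlap and 284 did not. Of the gene shares of lists, 5 moved beyond their intervals and 46 did not. Weak sites are limited to what was called, since the lowest summit held 28 reads in WT and 29 in KO. An effect of depth on them was not tested. The motif alternatives were not run. No paired analysis was possible because each genotype has 1 pooled list.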

Other observations

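The tests below were chosen after the results were seen, except the geometric mean test and the heat shock test, whose predictions were written before their results were seen. The genes with the most WT peaks were Rad51b (53 peaks, 28 kept), Tiam1 (35, 14 kept) and Ablim1 (32, 18 kept), which encode a DNA repair protein, a Rac activator and an actin-binding LIM protein. Their spans are long, at 551, 358 and 283 kb. Among 537 genes with at least 10 WT peaks, none kept all and none lost all. The number kept differed from that expected from WT reads by an SD of 1.27 peaks, against 1.19 from chance. The most kept beyond expectation were at Tcf12 (9 of 13, 4.52 expected), and the fewest at Nedd4l (7 of 19, 9.78 expected).

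The first pattern is the shorter KO list with fewer reads at its summits. A difference in ChIP depth would need unequal even-spread backgrounds, and their ratio was 1.00. A stricter KO limit is argued against as well, as far as the limit and the scaling go. With their WT reads under KO scaling, 100% of WT peaks would pass the lowest KO −log10 p of 4.49. Reads and WT background were scaled up together, which by itself raises −log10 p. The KO local background was not used, so a higher local background in KO is not covered. Lower enrichment of the KO pool as a whole remains a candidate explanation. Over the 3686 kept strong sites, the spread of the log2 ratio was 1.13 times that of counting alone. Counting makes up most of this spread, so modest differences between sites could be missed, and the 6 strong WT-only sites are not in it. The median ratio also rose with strength, from -0.96 to -0.75, so a single factor is at best approximate. Lower YAP binding at all sites in KO epidermis would look the same in 1 pool per genotype and stays open, untested.

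The second pattern is a slightly lower KO to WT ratio near gene ends, with medians of -0.92 and -0.87, a difference of -0.05 (resampling interval -0.07 to -0.01). Matched on WT reads it was -0.044 (-0.07 to -0.01), and matched on local background -0.046 (-0.08 to -0.01). Matching on either left the difference about as large, with intervals that exclude 0 but reach close to it, so at this precision weaker WT signal and input background stay open. An effect of genotype on these sites stays open, untested.

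The third pattern is the higher ratio at stronger sites, by 0.21 (0.19 to 0.24) on the log2 scale between the strongest and weakest of 5 bins of the sites with at least 120 WT reads. Selection on the WT count was predicted to leave no higher ratio in the strongest bin by the geometric mean of WT and KO reads. The difference was 0.22 (0.19 to 0.25) over 2517 stronger sites. Over all 14315 kept sites, where weak sites are selected on their KO reads, it was -0.03 (-0.05 to -0.02). KO counts were lower (median 84 against 146 reads at sites with at least 120 WT reads) and so relatively noisier. That by itself raises the ratio in bins of high geometric mean, so the test does not decide on selection. Removal of duplicate reads may contribute: undoing a limit of 1 read per position and strand left 0.17 with 600 evenly filled positions, 0.12 with 400 and 0.04 with 319, settings all tried after the values were seen. How reads fill positions is not known here, so duplicate removal, selection and an untested effect of genotype cannot be told apart.

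A hypothesis arose from the WT-only site near Bag3 that heat shock genes lose sites beyond what their strength predicts. In 34 further genes of that response not seen beforehand, 34 of 73 WT peaks within 10 kb were kept (46.6%), against 41.8% for peaks of equal reads, the 87.7th percentile. Within 100 kb the percentile was 87.9, so no loss specific to this group was found.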
